A study of Mus musculus with 384 samples.

How the data were processed

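The samples were single cells sorted for yellow fluorescent protein from 4 retinas of 2 mice at postnatal day 17, with 96 cells per retina. Per the submitters' processing notes, TopHat2 2.0.10, RSEM 1.2.28 and the mouse assembly mm10 were used, and the notes do not give the annotation, which is not known here. The authors deposited RSEM expected counts per gene and cell, which are not normalised. The authors also deposited TPM (transcript abundance scaled to a fixed total in each cell) per gene and cell. Both hold 32813 genes, 37 of them mitochondrial, for 383 of the 384 cells. The remaining cell, of retina 1la, had no values and was not analysed here. CPM (counts scaled to a fixed library total) were computed here from the deposited expected counts, after summing cells, with TMM-scaled library sizes. The Kcng4 levels per cluster are the exception, and used plain library totals and the clusters made from all genes. Intervals are given for numbers of cells and cover counting error only.

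Cells with at least 1500 genes detected and 50000 counts were kept, a gene counting as detected from an expected count of 1. This left out 50 cells, 22 of 1la, 11 of 1Ra, 4 of 2la and 13 of 2Ra. Kept cells were clustered with scanpy 1.11.5 on log2(TPM + 1), with 15 principal components and Leiden clustering at a resolution of 1. The number of variable genes (2000) and of neighbours (30) was taken from a grid as the pair with the highest agreement between random subsets of the genes (mean adjusted Rand index 0.847). This was done after the cells had been looked at and before any gene was tested. The tests, the filters, the gene lists, the marker lists, the rule for named genes and most alternatives were chosen before the data were examined.

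So that no gene defined the cluster it was tested in, the genes were split at random into 2 subsets, each subset was clustered alone, and each gene was tested with the labels from the other subset. The overlap of the 2 label sets (Jaccard index) was 0.867 for the Sox6-high, 0.950 for the Igfn1-high, 0.866 for the Lrrtm1-high, 0.730 for the mixed, 0.917 for the rod-gene and 0.630 for the low-RNA cluster. Cell numbers, shares and leading genes come from clustering on all genes. The rule for naming clusters asked for at least 3 markers that were detected and led the cluster. The part on leading genes was not met by any bipolar-like cluster, since most kept cells shared these markers, so the name bipolar-like rests on detection alone and departs from that rule. No subtype name was given. Marker lists covered rods, cones, bipolar cells and their rod, OFF, type 5, type 6, type 7 and type 8 and 9 kinds, ganglion cells, alpha ganglion cells, amacrine cells, horizontal cells, Müller glia, astrocytes, microglia, endothelium, pericytes and pigment epithelium.

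Rounded expected counts were summed per mouse and cluster and tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3, limma 3.58.1), with the mouse as a block and each cluster against the mean of the others, not against each of them. These contrasts are not independent, so a gene that stands apart in 1 cluster also shifts the contrasts of the others. Genes were kept by filterByExpr, and 16421 were tested. A call was a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Clusters needed 5 cells in each mouse. The mixed cluster had 5 cells in mouse 1 by all genes, and 3 and 7 by the labels of the 2 subsets, so it was left out of this fit. The counts with and without it had both been seen before this was settled, and both are given. Ra and la retinas were compared in sums per retina over 270 cells of the 4 bipolar-like clusters, the mixed cluster included, without a block and with the mouse as a block. Mouse 1 and mouse 2 were compared without a test, counting genes that differed at least 4-fold in mean CPM, with both retinas of 1 mouse at least 2-fold above both of the other and a mean of at least 50 CPM. The comparison of ganglion-like with bipolar-like cells could not be made for lack of a ganglion-like cluster, and none of its alternatives was run.

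Named genes were up to 12 higher and up to 12 lower per cluster with the largest absolute log2 fold change among calls with the same direction in both mice and at least 50 CPM on the higher side. The same rule was applied to calls from retina sums, of which the text names only a few examples per cluster, picked after their values were seen, and leaves most out. List members were named as examples, the 6 largest on each side were taken between Ra and la retinas, and Kcng4 was always named. Some further results are not reported here. The fixed lists were the ON pathway, ionotropic glutamate receptors, GABA and glycine receptors, potassium and HCN channels, sodium channels, calcium channels, release machinery and ribbon, neurofilaments and axon, neuropeptides, adhesion and guidance, transcription factors, and immediate early and heat shock genes. Gene positions are those of the GENCODE annotation on this assembly, matched by symbol.

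Alternatives were sums per retina with the retina as a block, no block, DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, at least 3000 or 500 genes per cell, labels from all genes, other Leiden resolutions, 30 principal components, clustering on log2(CPM + 1), a 2-fold rule, mean TPM over cells, the largest cluster alone and each retina left out. Fits with the mixed cluster, without cells rich in rod transcripts, and without the mixed cluster in the retina comparisons were added after seeing the data. The fit was tested on simulated data made from the mouse sums, with 50 genes changed at each size in the Lrrtm1-high cluster among 15924 genes. It recovered 0% of 2-fold, 26% of 4-fold, 68% of 16-fold and 86% of 64-fold changes, with 5 false calls. Before the change, each simulated gene had 1 mean level for all clusters and both mice, so these shares need not hold for the real sums. In the real mouse sums Grm6, at a log2 fold change of -7.34 in the Lrrtm1-high cluster, was not called. This test was written after the real fit had first been run. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9.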

Results

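The series holds single-cell transcriptomes of fluorescent cells sorted from the retina of 2 mice at postnatal day 17. The mice carried a Cre recombinase driven from the Kcng4 locus together with a Thy1-based yellow fluorescent protein reporter that Cre switches on, so the sort took cells with a present or past activity of Kcng4, a modifier subunit of voltage-gated potassium channels. Each of 4 retinas, named 1la, 1Ra, 2la and 2Ra after the mouse and a suffix that the labels do not spell out, gave 96 cells, each processed by Smart-seq2, a full-length cDNA method. Of the 384 cells, 383 had values, and 1 cell of retina 1la was not analysed here. There was no treatment. The comparisons that the design allows are between the kinds of cell that the sort held, between the retinas of 1 mouse and between the mice. Each retina filled its own set of 96 wells. A difference between retinas or between mice therefore cannot be told apart from a difference between these sets of wells. The mouse is the replicate (n = 2), and the cells are not.

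A filter of at least 1500 genes detected and 50000 counts kept 333 of the 383 cells, of which 73 came from retina 1la, 85 from 1Ra, 92 from 2la and 83 from 2Ra. The total count of the kept cells ranged from 203657 to 1945582 with a median of 1054046, and the median number of genes detected was 6320. The median total per retina was 1240786 in 1la, 746530 in 1Ra, 1185059 in 2la and 1052926 in 2Ra. The median share of counts from mitochondrial genes was 2.09% in 1la, 2.17% in 2la, 4.28% in 1Ra and 4.88% in 2Ra. No pair of kept cells had a correlation of log counts above 0.95, and the highest was 0.77, so no cell appeared to be deposited more than once.

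The first question was which cell classes the Kcng4 line labels. The kept cells fell into 6 clusters, and the bipolar-like ones, named by a leading gene, made up most of them. The largest, called Sox6-high here, held 113 cells or 33.9% of the kept cells (95% Clopper-Pearson interval 28.9% to 39.3%). It was led by Sox6, a transcription factor, and included among its first 10 genes Htr3a, a serotonin receptor subunit, Cabp5, a calcium-binding protein of bipolar cells, and Grm6, the glutamate receptor of ON bipolar cells. Of the 7 type 5 bipolar markers, 3 were at 1 TPM or more in most of its cells: Sox6 in 98.2%, Htr3a in 85% and Kcng4, which the sort selects for, in 97.3%. Only Sox6 and Htr3a were among its 15 leading genes, and the rod-gene and mixed clusters had 4 and 3 of the 7, so no subtype name was given. The Igfn1-high cluster held 61 cells, a share of 18.3% (14.3% to 22.9%), and was led by Igfn1, Sec1, Cabp2 and Vsx1, the last a transcription factor of some bipolar types. It had 2 of the 3 type 7 bipolar markers in most cells, Igfn1 in 88.5% and Kcnab1 in 90.2%, which is under the 3 that a subtype name needs. The Lrrtm1-high cluster also held 61 cells, a share of 18.3% (14.3% to 22.9%), and was led by Gsg1, Kirrel3, Lrrtm1, a synaptic adhesion protein, and Ddit4l. It had 2 of the 7 type 5 markers and 1 of the 4 type 6 markers in most cells. Of the 12 general bipolar markers, 11, 12 and 9 were at 1 TPM or more in most cells of the Sox6-high, Igfn1-high and Lrrtm1-high clusters, and they are called bipolar-like for that reason.

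The remaining cells formed 3 clusters. The mixed cluster held 35 cells, a share of 10.5% (7.43% to 14.3%), had all 12 bipolar markers in most cells, which makes it bipolar-like too, and the highest median number of genes, 8060, and was led by Cdr1 and Pcp4l1. The rod-gene cluster held 47 cells, a share of 14.1% (10.6% to 18.3%). Its first 10 genes were transcripts of rod photoreceptors such as Gnat1 and Pdc, while 11 of the 12 bipolar markers were also present in most of its cells, so it was left unnamed. Its median Sox6 level was 149 TPM, against 199 TPM in the Sox6-high, 20.8 in the mixed and 0 in the Igfn1-high and Lrrtm1-high clusters. The Sox6-high share therefore leaves out cells of this cluster that also held Sox6. The low-RNA cluster held 16 cells, a share of 4.80% (2.77% to 7.69%), with a median of 2126 genes and a median mitochondrial share of 9.98%. It was led by Nefl, which is on the ganglion cell list, and Calb1, and was left unnamed as well. No cluster was ganglion-like by markers found in most of its cells, a rule that cannot show a few ganglion cells within a cluster. The mean log2(TPM + 1) over the ganglion list was 0.896 in the low-RNA cluster and 0.191 to 0.39 in the others. At most 1 of the 10 ganglion cell markers and 1 of the 5 alpha ganglion cell markers, the latter a list that includes Kcng4 itself, reached 1 TPM in most cells of any cluster, Thy1 being the ganglion marker that did so, and the planned comparison of ganglion-like with bipolar-like cells could not be made.

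Some markers of other retinal classes were found in most cells. Calb1, on the horizontal cell list, was at 1 TPM or more in 100% of the cells of every cluster, Pax6, on the amacrine list, in 77% to 94.3%, and Glul, on the Müller glia list, in 45.9% to 90.2%. No marker of astrocytes, microglia, endothelium, pericytes or pigment epithelium reached 1 TPM in most cells of any cluster. At most 1 of the 7 cone markers, 1 of the 6 rod bipolar markers, 2 of the 9 OFF bipolar markers, 2 of the 3 markers of type 8 and 9 bipolar cells, 2 of the 8 amacrine markers, 2 of the 5 horizontal cell markers and 2 of the 8 Müller glia markers did so in a cluster. Of the 8 rod markers, all 8 did so in the rod-gene cluster, and 1 to 3 in each of the others.

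The Sox6-high share was 28.8% in retina 1la, 35.3% in 1Ra, 39.1% in 2la and 31.3% in 2Ra, with overlapping counting intervals. The Igfn1-high share was 25.3% in mouse 1 (18.7% to 32.8%) and 12% in mouse 2 (7.58% to 17.8%). The intervals overlapped with log2(CPM + 1) clustering (14.3% to 27.4% and 6.21% to 15.8%) and at 500 genes per cell (12.4% to 24.5% and 5.29% to 14.3%). The mixed cluster, which shared leading genes such as Pcp4l1 with it, went the other way, with 3.2% in mouse 1 and 17.1% in mouse 2. The Lrrtm1-high share was 19.6% in mouse 1 and 17.1% in mouse 2. The mixed cluster made up 26.5% of the cells of retina 2Ra (17.4% to 37.3%), 8.70% in 2la, 2.35% in 1Ra and 4.11% in 1la, and it dissolved into other clusters at a coarser clustering. The low-RNA cluster had 0 of 83 cells in 2Ra, which allows a share of up to 4.35%, and between 4.71% and 9.59% in the other retinas. These intervals cover counting error only, and with 2 mice no test of shares was made. The recovery of each class also depends on the sort and on the set of wells, which was a separate one for each retina.

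**Figure D1:**
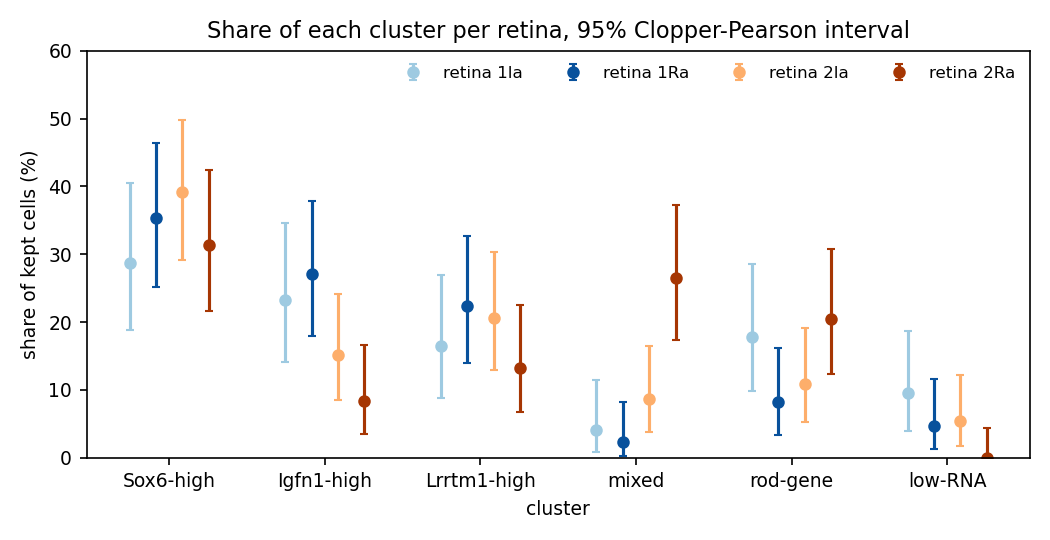
Share of the kept cells (%) that each of the 6 clusters took in each of the 4 retinas, with 1 point per retina and bars for the 95% Clopper-Pearson interval, which covers counting error only. The Sox6-high cluster had the highest share in each retina at these settings, but in 2Ra the rod-gene cluster was above it at a Leiden resolution of 0.5 (47% against 31.3%) and with 30 principal components (37.3% against 31.3%), and the mixed cluster reached 26.5% in retina 2Ra.

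Kcng4 is the gene whose locus drives the Cre recombinase that switches on the reporter, and it was among the 15 leading genes of no cluster. Its level was 698 ± 27.6 CPM (mean ± SD, n = 2 mice) in the Sox6-high cluster and 688 ± 181 CPM in the Lrrtm1-high cluster. It was 190 ± 29.4 CPM in the Igfn1-high cluster, 453 ± 162 CPM in the rod-gene cluster, 142 ± 90.8 CPM in the mixed cluster and 162 ± 227 CPM in the low-RNA cluster. At least 1 count of Kcng4 was found in 96.1% and 100% of the Sox6-high cells of mouse 1 and mouse 2, and in 75% and 95.2% of the Igfn1-high cells. Kcng4 lies on chromosome 8 from 119623854 to 119635680 (mm10).

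The 3 clear bipolar-like clusters were then compared with each other to find what sets them apart. The Igfn1-high cells had high levels of a chloride channel, an extracellular matrix protein and a protein of vesicle release and lower levels of 3 transcription factors. Reln, which encodes the secreted protein reelin, was at 2457 ± 263 CPM in the Igfn1-high cluster (n = 2 mice here and in all values below), 487 ± 28.7 CPM in the Sox6-high cluster and 112 ± 9.21 CPM in the Lrrtm1-high cluster. Snap25, a core protein of synaptic vesicle fusion, was at 2821 ± 17 CPM against 947 ± 24.7 and 828 ± 31.3 CPM. Best3, of the bestrophin chloride channel family, was at 213 ± 56.8 CPM and at 0.0740 and 0.0437 CPM in the Sox6-high and Lrrtm1-high clusters. Gnb3, the G protein beta subunit of ON bipolar cells, was at 3903 ± 748 CPM in the Igfn1-high cells, 2214 ± 436 in the Sox6-high cells and 701 ± 64.7 in the Lrrtm1-high cells. These were the 4 genes higher in the Igfn1-high cluster than in the mean of the others in edgeR's quasi-likelihood test, and each of them has a Benjamini-Hochberg adjusted p of 0.020 and the same direction in both mice. The log2 fold change was 3.39 ± 0.10 (SE) for Reln, 1.67 ± 0.06 for Snap25 and 1.64 ± 0.07 for Gnb3. The Gnb3 call rests in large part on its low level in the Lrrtm1-high cells, since the Sox6-high cells were nearer, at 2214 against 3903 CPM.

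The same test found 7 genes lower in the Igfn1-high cluster. Nfia, a nuclear factor I transcription factor, was at 4.32 ± 2.15 CPM there and at 1063 ± 2.80 and 1435 ± 50.3 CPM in the Sox6-high and Lrrtm1-high clusters (log2 fold change -8.22 ± 0.39, adjusted p 0.028). Neurod4, a basic helix-loop-helix factor, was at 706 ± 7.27 CPM against 3679 ± 23.5 and 3729 ± 472 CPM. Esrrg, an orphan nuclear receptor, was at 14.7 ± 3.18 CPM against 545 ± 45.7 and 1466 ± 149 CPM. Kcnh6, a potassium channel of the ether-a-go-go family, was at 34.4 ± 13.5 CPM against 1863 ± 359 and 1352 ± 311 CPM. Lrrtm1, Ddit4l and Hmcn2 were the other 3, at 1.08, 0.510 and 12.3 CPM in the Igfn1-high cluster. The adjusted p was 0.039 for Hmcn2 and 0.020 for the remaining 5.

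In the Lrrtm1-high cluster 4 genes were higher and 3 lower than in the mean of the others. Lrrtm1 was at 1170 ± 106 CPM against 94.2 ± 9.10 CPM in the Sox6-high cells (log2 fold change 6.87 ± 0.23, adjusted p 0.025), and Ddit4l, a regulator of the growth kinase mTOR, was at 558 ± 26.1 CPM against 5.54 ± 1.04 CPM (8.40 ± 0.22, adjusted p 0.020). Esrrg (log2 fold change 4.03 ± 0.18, adjusted p 0.038) and Kcnh6 (2.43 ± 0.12, adjusted p 0.048) were the other 2, and the Kcnh6 call rests on its low level in the Igfn1-high cells, since the Sox6-high cells had more of it. The lower genes were Reln (-3.29 ± 0.13, adjusted p 0.029), Gnb3 (-2.06 ± 0.08, adjusted p 0.029) and Gabrr2, a GABA-C receptor subunit, which was at 433 ± 102 CPM against 2217 ± 147 and 2013 ± 208 CPM (-2.30 ± 0.11, adjusted p 0.048).

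No gene passed in the Sox6-high cluster in this test, where 1482 of 16421 genes had an unadjusted p under 0.05. In sums per retina with the retina as a block, 93 genes were higher and 13 lower there, and DESeq2's Wald test on the mouse sums called 759 genes. The genes called in the retina sums include Sox6 itself, at 600 ± 27.8 CPM against 0.300 ± 0.144 in the Igfn1-high and 18.3 ± 12.2 in the Lrrtm1-high cells, Htr3a at 476 ± 95.9 CPM against 5.37 and 132 CPM, Ptprt, a receptor phosphatase, at 242 ± 5.97 CPM against 0.183 and 3.94 CPM, and Ngfr, the low-affinity neurotrophin receptor, at 219 ± 15.3 CPM against 3.47 and 40.3 CPM. Cacna1e, a calcium channel subunit, was at 74.4 ± 32.3 CPM against 0.0223 and 7.49 CPM. In the same retina sums the Igfn1-high cluster had 172 genes higher and 120 lower, with Igfn1, Sec1, Cabp2, Vsx1 and Unc13c among the higher, and all 11 genes of the mouse sums were called again. The Lrrtm1-high cluster had 82 higher and 87 lower, with Kirrel3 at 925 ± 333 CPM among the higher and Grm6, Fn1 and Il1rapl2 among the lower, and all 7 genes of the mouse sums were called again. The 2 retinas of a mouse are not independent animals, so adjusted p values from retina sums are too small as a statement about mice.

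The counts from mouse sums depend on single retinas and on the cells and clusters in the fit. In the order Sox6-high, Igfn1-high and Lrrtm1-high, edgeR called 0, 0 and 0 genes without retina 1Ra (993, 1438 and 1263 at an unadjusted p under 0.05), 0, 1 and 2 without 2Ra, 1, 10 and 0 without 2la, and 2, 15 and 11 without 1la. Rod transcripts were not spread evenly: 13 of the 61 Igfn1-high cells, 4 of the 61 Lrrtm1-high cells and 4 of the 113 Sox6-high cells had a summed TPM of the rod markers of at least 1000, and without such cells 0 (1358 at an unadjusted p under 0.05), 6 and 4 genes were called, with 6 of the 11 Igfn1-high and 3 of the 7 Lrrtm1-high calls among them. At 3000 genes per cell 1 of the 7 Lrrtm1-high calls was left. With the mixed cluster in the fit 5 and 14 genes were called in the Igfn1-high and Lrrtm1-high clusters, and only 5 of the 11 and 4 of the 7 calls were among them.

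**Figure D2:**
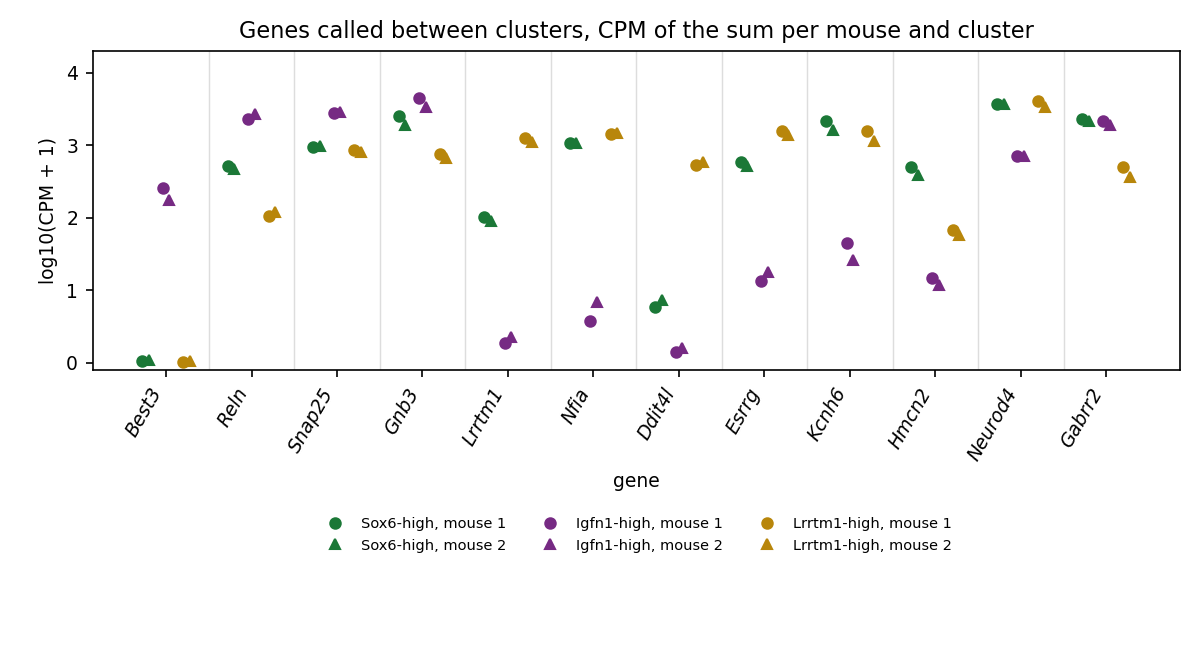
Level of each of the 12 genes called in the mouse sums, as log10(CPM + 1), in the Sox6-high, Igfn1-high and Lrrtm1-high clusters, with a circle for mouse 1 and a triangle for mouse 2. Both mice gave similar values in each cluster, as for Snap25 with 2821 CPM in the Igfn1-high cells and 947 and 828 CPM in the others.

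In the ON pathway list, whose genes serve the depolarising light response of bipolar cells, 1 of 12 members was called lower in the Lrrtm1-high cluster over all genes tested, and 6 were lower and 1 higher adjusted over the list alone. Counts per cluster in this and the other lists are not independent, since each cluster enters the mean that the others are set against. Grm6 was at 11.3 ± 12.9 CPM in that cluster against 1610 ± 73.5 CPM in the Sox6-high and 1211 ± 4.45 CPM in the Igfn1-high cells. Pcp2 was at 16.4 ± 6.37 CPM against 596 ± 225 and 921 ± 85.4 CPM, Gng13 at 24.6 ± 4.44 CPM against 140 ± 5.27 and 194 ± 11.2 CPM, and Trpm1, the cation channel of the pathway, at 620 ± 77.6 CPM against 1711 ± 314 and 1205 ± 11.5 CPM. Gpr179 was at 339 ± 44.9 CPM against 380 ± 46.5 and 532 ± 53.2 CPM and did not pass. The member called over all genes was Gnb3, and 5 were called lower in the retina sums. In the Igfn1-high cluster 1 was called higher over all genes, and 5 were higher and 1 lower adjusted over the list alone. The lower one was Cabp5, at 23.2 ± 23.7 CPM against 1749 ± 39.8 and 1815 ± 374 CPM. In the Sox6-high cluster none was called over all genes and 5 were higher adjusted over the list alone, among them Nyx, at 233 ± 70.5 CPM against 47.4 ± 18.9 and 46.6 ± 4.18 CPM.

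**Figure D3:**
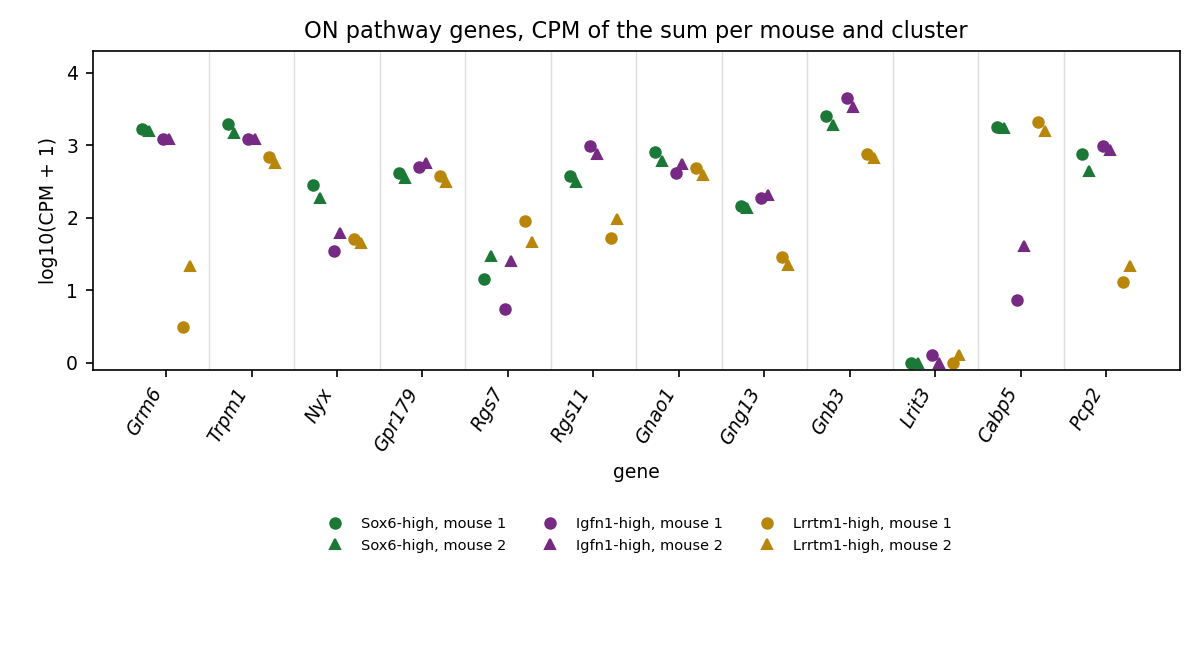
Level of the 12 genes of the ON pathway list, as log10(CPM + 1), in the 3 clusters, with a circle for mouse 1 and a triangle for mouse 2. In the Lrrtm1-high cluster Grm6 was at 11.3 CPM on average, with the mice apart, and in the other clusters at 1610 and 1211 CPM.

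Of 45 tested members of the transcription factor list, 3 were called lower in the Igfn1-high cluster over all genes (Nfia, Neurod4 and Esrrg), and 4 were higher and 11 lower adjusted over the list alone. Vsx1 was at 672 ± 7.29 CPM against 0.887 and 2.08 CPM, and Lhx4 at 14 ± 18.4 CPM against 778 ± 119 and 863 ± 69.5 CPM, both passing adjusted over the list alone. Meis2 was at 3.89 ± 2.98 CPM in the Igfn1-high, 362 ± 9.49 in the Sox6-high and 963 ± 148 in the Lrrtm1-high cells. In the Lrrtm1-high cluster 1 was called higher over all genes, and 6 were higher and 1 lower adjusted over the list alone, with Irx3 among the higher, at 48.4 ± 5.78 CPM and at 0.0506 CPM in the Sox6-high cells. In the Sox6-high cluster none was called over all genes, and 8 were higher and 1 lower adjusted over the list alone, with Sox6 and Bhlhe23 (178 ± 6.78 CPM against 18.1 ± 5.74 and 50 ± 2.00 CPM) among the higher and Vsx1 the lower one. The Vsx1 pass rests on its high level in the Igfn1-high cells, since the Lrrtm1-high cells also had little of it. Otx2 and Isl1 did not pass in any cluster. Otx2 was at 754 ± 58.9, 612 ± 105 and 779 ± 156 CPM, and Isl1 was at 733 ± 93, 444 ± 122 and 720 ± 3.21 CPM in the Sox6-high, Igfn1-high and Lrrtm1-high cells.

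Of 74 tested members of the adhesion and guidance list, none was called over all genes in the Sox6-high cluster, and 1 was called over all genes in the Igfn1-high and 1 in the Lrrtm1-high cluster, in both cases Lrrtm1. Adjusted over the list alone, 13 were higher and 12 lower in the Igfn1-high, 12 higher and 7 lower in the Lrrtm1-high, and 6 higher and 1 lower in the Sox6-high cluster. Sdk1 and Sdk2, the sidekick adhesion proteins, were at 42 ± 3.88 and 67.2 ± 21.1 CPM in the Igfn1-high cells and under 5 CPM in the others. Epha7, an ephrin receptor, was at 44.6 ± 15.9 CPM there against 1499 ± 221 and 1745 ± 521 CPM, and Epha4 was at 0.806 ± 0.622 CPM in the Lrrtm1-high cells against 96.4 ± 11.9 and 154 ± 36.6 CPM. Pcdh9 was at 777 ± 71.4 CPM in the Igfn1-high cells against 162 ± 21.9 and 219 ± 10 CPM.

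Among ion channels, no member of the potassium and HCN, sodium or calcium channel lists was called over all genes in any cluster. Kcnh6, the potassium channel gene called in the Igfn1-high and Lrrtm1-high clusters, is not on these lists. Adjusted over the list alone, 6 of the 34 tested potassium and HCN channel genes were higher and 9 lower in the Igfn1-high cluster, 8 higher and 2 lower in the Lrrtm1-high cluster, and 1 higher and 1 lower in the Sox6-high cluster. Kcnma1, the large-conductance calcium-activated channel, was at 1387 ± 126 CPM in the Igfn1-high, 472 ± 78.9 in the Sox6-high and 35.7 ± 32.2 in the Lrrtm1-high cells. Of 18 calcium channel genes, 2 were higher and 3 lower in the Igfn1-high cluster, 2 were lower in the Lrrtm1-high cluster and 1 was higher in the Sox6-high cluster, with Cacna2d3 at 305 ± 44.3 CPM in the Igfn1-high cells against 27.9 ± 6.07 CPM in the Sox6-high and 11.4 ± 3.36 CPM in the Lrrtm1-high cells. Of 7 sodium channel genes, 1, Scn3a, was higher in the Lrrtm1-high cluster at 93.4 ± 6.44 CPM against 21.6 ± 3.93 and 22.8 ± 6.51 CPM.

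None of the 15 ionotropic glutamate receptor genes passed in any cluster, over all genes, adjusted over the list alone or in the retina sums. Gria2 was at 326 ± 67.3, 542 ± 65.3 and 351 ± 48 CPM in the Sox6-high, Igfn1-high and Lrrtm1-high cells. Of 14 GABA and glycine receptor genes, Gabrr2 was the only one called over all genes, and 2 were higher in the Igfn1-high, 2 higher and 2 lower in the Lrrtm1-high, and 1 higher and 1 lower in the Sox6-high cluster adjusted over the list alone. Of 24 release and ribbon genes, Snap25 was the only one called over all genes, and Cplx1 and Cplx2, the complexins, were higher in the Lrrtm1-high cluster adjusted over the list alone, the second at 71.9 ± 4.68 CPM against 25.4 ± 0.0664 and 19.9 ± 5.71 CPM. Of 11 neurofilament and axon genes none was called over all genes, and 3 were higher and 1 lower in the Igfn1-high cluster and 2 higher and 2 lower in the Sox6-high cluster adjusted over the list alone. Of 6 neuropeptide genes none was called over all genes. Adjusted over the list alone, 1 was higher and 1 lower in the Sox6-high cluster, 1 higher in the Igfn1-high cluster and 1 higher and 1 lower in the Lrrtm1-high cluster. Gal, the precursor of galanin, was at 36.3 ± 0.986 CPM in the Sox6-high cells, at 0 CPM in the Igfn1-high cells and at 0.0337 CPM in the Lrrtm1-high cells. Of 12 immediate early and heat shock genes none was called over all genes. Adjusted over the list alone, 3 were higher in the Sox6-high cluster, 1 was lower in the Igfn1-high cluster, and 1 was higher and 1 lower in the Lrrtm1-high cluster.

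On the assembly mm10, Reln lies on chromosome 5 from 21884454 to 22344702, Snap25 on chromosome 2 from 136713453 to 136782428, Gnb3 on chromosome 6 from 124834240 to 124840275, Nfia on chromosome 4 from 97772734 to 98118874, Lrrtm1 on chromosome 6 from 77242689 to 77257791, Gabrr2 on chromosome 4 from 33062999 to 33095865 and Grm6 on chromosome 11 from 50850685 to 50866208. All are protein-coding genes.

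The Ra and la retinas were compared over the 270 cells of the 4 bipolar-like clusters. Each retina was also its own set of wells, and the 2 cannot be told apart. Mitochondrial transcripts made up 4.52% and 5.05% of the summed counts in 1Ra and 2Ra, and 2.31% and 2.27% in 1la and 2la. No gene passed edgeR's quasi-likelihood test between 2 Ra and 2 la retinas, where 1738 of 17382 genes had an unadjusted p under 0.05. With the mouse as a block the count was also 0, with 1512 genes at an unadjusted p under 0.05, while DESeq2's Wald test called 425 genes higher and 167 lower in Ra. Among genes with the same direction in both mice, the largest differences on the Ra side included those of Hmgn5, Cdr1, Haus2, Usmg5 and mt-Nd6. Cdr1 was at 290 ± 101 CPM in Ra and 63 ± 6.34 CPM in la (n = 2 retinas), and mt-Nd6 at 263 ± 63.8 and 65.4 ± 0.939 CPM. On the la side the largest were 2610507B11Rik, Acvr1b, Slc38a7, Calb1, Rtn4rl1 and Zfp804b, with Zfp804b at 181 ± 50.9 CPM in la and 58.2 ± 6.38 CPM in Ra. None of these genes passed, and the adjusted p ranged from 0.345 to 0.412.

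Mouse 1 and mouse 2 can be set side by side only as values, with 1 animal on each side. By the rule of a 4-fold difference, 0 genes were higher in mouse 1 and 5 in mouse 2. These were Gad1, a GABA synthesis enzyme of amacrine cells, Dkk3 and Vim, which are found in Müller glia, Chrna6, a nicotinic receptor subunit, and Xlr3b, a gene of a multi-copy family on the X chromosome whose reads cannot be assigned to it with certainty. Gad1 was at 94.3 CPM in 2Ra and 6.23 CPM in 2la against 0.0740 and 0.594 CPM in 1Ra and 1la, and Dkk3 was at 249 CPM in 2Ra and 18.9 CPM in 2la against 7.34 and 8.19 CPM. Without the mixed cluster 2 genes were higher in mouse 1 and 1 in mouse 2, and 1 of these 3 was among the 5, so the one-sided result did not hold without that cluster. Leaving out 1 retina gave 13 genes without 1la, 20 without 1Ra, 21 without 2la and 7 without 2Ra. With that cluster kept, these split into 1 higher in mouse 1 and 12 in mouse 2, 2 and 18, 3 and 18, and 2 and 5. With a retina left out, 1 side has only 1 retina, and the part of the rule on both retinas is easier to pass. A higher count there does not by itself show that the result rests on that retina. Xist, the transcript of X inactivation, was at 2311 ± 349 CPM in mouse 1 and 2338 ± 372 CPM in mouse 2 (n = 2 retinas). Of the Y-linked genes, Ddx3y, Eif2s3y and Kdm5d were at or under 1.44 CPM in all 4 retinas, and Uty was between 2.08 and 4.74 CPM.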

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

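All tests in this part were chosen only after the result was seen. No biological explanation was tested, because the design has no group that gives one. Gad1, a marker of amacrine cells, was at 94.347 CPM in the bipolar-like cells of retina 2Ra, far from the other 3 retinas by Dixon's test. The same value had already put Gad1 first in the comparison of the mice, so this test restates it and adds no support. Chance alone marks about 1 quantity in 20, and 14 quantities with 28 sides were tested. A single mark among them can therefore arise by chance. The 47 cells of the rod-gene cluster and the 16 cells of the low-RNA cluster entered no comparison between clusters.

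The rod-gene cluster combined rod transcripts with bipolar markers. Free rod RNA at a similar level in all wells is argued against, since the median summed TPM of the rod markers was 72.016 times that of the Sox6-high cluster (5068 against 70.4). A rod, or part of one, in the same well remains a candidate explanation, since a cell held a median of 8 of the 8 rod markers. Sox6 was at a median of 149 TPM in the rod-gene and 199 TPM in the Sox6-high cluster, and at 0 in the Igfn1-high and Lrrtm1-high clusters. In the rod-gene cells the 12 bipolar markers of the fixed list stood at a median of 70.5% of their level in the Sox6-high cluster (quartiles 65.6% and 89.8%), and 10 of the 12 were lower. Their mean log2(TPM + 1) was 7.315 in the Sox6-high, 7.014 in the rod-gene, 6.689 in the Igfn1-high, 6.638 in the mixed and 4.991 in the Lrrtm1-high cluster. A level under that of the Sox6-high cluster therefore does not by itself show dilution by a rod. An earlier form of this test used genes picked for a high level in the Sox6-high cluster, which would fall in any other group, and was replaced.

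The mixed cluster took 22 of its 35 cells from retina 2Ra. Deeper sequencing is argued against, since after thinning every cell to 100000 counts its median number of genes was still 1.391 times that of the Sox6-high cluster (5453 against 3919). More than 1 cell in a well may contribute: 11.429% of its cells, 4 in number, had Sox6 and Igfn1 both at 10 TPM or more, against 1 of 235 cells in the 3 other bipolar-like clusters. Wells of 2 cells drawn at random would hold a Sox6-high and an Igfn1-high cell in 12.4% of cases by the shares in all retinas and in 5.28% by those in 2Ra, both inside the interval of the observed share (3.20% to 26.7%, Clopper-Pearson), so the bound of over 50% first set for this explanation was too high, and with 4 cells it stays open. The mean summed TPM of the Müller glia markers was 1213 in it and 185 to 289 in the 3 other bipolar-like clusters, that of the amacrine markers was 309 against 24 to 53.2, and Dkk3 was at 1 TPM or more in 34.3% of its cells against 1.6% to 8% in those clusters, while Apoe was at 10 TPM or more in 7 of its 35 cells and in 15 of the 61 Lrrtm1-high cells. The type 8 and 9 and the OFF bipolar lists also had their highest mean log2(TPM + 1) in it, 2.302 and 1.578. The Igfn1-high cluster came next, with 1.928 and 1.456. The type 5, 6 and 7 lists were highest in other clusters. Grik1, on the OFF list, was at 10 TPM or more in 12 of the 35 mixed cells and in 19 of the 113 Sox6-high cells. Whether the mixed cluster holds other bipolar kinds was not tested.

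Grm6 was low in the Lrrtm1-high cluster. A lower depth or yield is argued against, since the median number of genes per cell was 1.005 times that of the Sox6-high cluster. A first form of this test, whether Grm6 was missing where Trpm1 was found, decided nothing and was replaced, with Grm6 detected in 72.1% and Trpm1 in 100% of the cells. A test of the Grm6 difference without cells rich in rod transcripts, where the log2 fold change was -7.35 against -7.34 with them and so argued against rods as the diluting cells, was replaced as well. Dilution that lowers all transcripts alike is argued against, since 156 genes at 500 CPM or more in both other clusters stood at a median of 93.275% of their level there (quartiles 70.7% and 107%), and Grm6 at 0.798%. These genes were picked by level alone and may include ones that the diluting cells also express. The values therefore cannot exclude dilution of bipolar transcripts alone.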

How the results depend on the processing

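The fits with the mixed cluster, without cells rich in rod transcripts and without the mixed cluster between retinas were added after seeing the data, and all other alternatives were chosen before. Counts of called genes are given in the order Sox6-high, Igfn1-high and Lrrtm1-high, where the mouse sums gave 0, 11 and 7, and the cause of each change was not tested. With retinas as the replicate block the counts were 106, 292 and 169, and retinas of 1 mouse are not independent animals. The DESeq2 Wald test called 759, 1390 and 1110. Labels from all genes, which lets a gene define its cluster, gave 3 and 19 in the first and second. With no replicate block 110 and 60 were called in the second and the last. At least 3000 genes per cell gave 1 in the last. Without cells rich in rod transcripts 6 and 4 were called, and with the mixed cluster 5 and 14. The decision to leave that cluster out was settled after both versions had been seen. Leaving out each retina gave 0 to 2, 0 to 15 and 0 to 11, so these counts rest on single retinas. Members of the fixed lists called were 0, 6 and 4, and became 20, 43 and 29 with the retina block, 66, 102 and 84 with the DESeq2 Wald test, 1 and 10 with labels from all genes, 24 and 17 without a block, 1 (Lrrtm1-high) at 3000 genes per cell, 3 and 2 without cells rich in rod transcripts, 3 (Igfn1-high) with the mixed cluster, and 0 to 1, 0 to 7 and 0 to 6 without each retina. Between Ra and la retinas, the DESeq2 Wald test called 592 genes and edgeR 0 (1738 at an unadjusted p under 0.05), also 0 with the mouse as a replicate block and without each retina. Between the mice, 5 genes became 12 by the 2-fold rule, 2 by mean TPM, 3 without the mixed cluster and 7 to 21 without each retina. The rule between the mice is easier to pass with a retina left out, since 1 side then has only 1 retina. The Igfn1-high share was 13.37% at 500 genes per cell and the low-RNA share 0.0% at 3000. At a Leiden resolution of 0.5 the mixed share was 0.0% and the rod-gene share 24.32%, and with 30 principal components they were 3.9% and 20.12%. Of 2275 values of 176 pairs of a named gene and a cluster, 0 changed sign, 1921 stayed on their side of the threshold, 279 passed it newly and 75 no longer passed. Most of these pairs were not called in the mouse sums, being list members that passed over a list alone, or Kcng4. Only the 11 and 7 calls could be lost, and 18 were lost without 1Ra and 15 without 2Ra. Apart from Kcng4, the pairs were picked for differences in these same data, so a kept sign says little. Of the shares per retina, 129 stayed within the counting interval and 15 did not. The comparison with ganglion-like cells, and its alternatives, were not run. On simulated data with 2 mice, 0% of 2-fold and 26% of 4-fold changes were recovered, so a gene that was not called is not shown to be unchanged. How much of this is due to depth was not tested.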

Other observations

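Several list members that were not called over all genes passed adjusted over their lists alone (n = 2 mice, chosen after their values were seen). Scg2, a secretogranin, was at 647 ± 120 CPM in the Lrrtm1-high cells, 284 ± 74.9 in the Igfn1-high cells and 137 ± 44.1 in the Sox6-high cells. Bdnf, a neurotrophin, was at 4.25 ± 0.213, 65.7 ± 14.2 and 27 ± 9.77 CPM, in that order. Ank3, an organiser of the axon initial segment, was at 789 ± 40.9 CPM in the Igfn1-high cells against 253 ± 14.4 in the Sox6-high and 388 ± 7.87 in the Lrrtm1-high cells. Adjusted over the list alone, Scg2 was higher in the Lrrtm1-high and lower in the Sox6-high cluster, Bdnf was higher in the Igfn1-high and lower in the Lrrtm1-high cluster, and Ank3 was higher in the Igfn1-high and lower in the Sox6-high cluster.

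Kcng4 can also be given, without a test, as a share of its level in the Sox6-high cluster. It was 27.3% in the Igfn1-high, 98.1% in the Lrrtm1-high, 64.4% in the rod-gene, 20.6% in the mixed and 22.6% in the low-RNA cluster by CPM, and 28.9%, 97.5%, 61.9%, 19.1% and 27% by mean TPM.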
